A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

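RNA-seq was made from 4 cultures of E. coli K-12 MG1655, 2 on galactose and 2 on glucose, each sample's group and replicate number being taken from its title. Per the labels' protocols, RNA was stabilised with RNAprotect and isolated as total RNA with an RNeasy kit. The same protocol text also describes a chromatin assay that was not used here. The library kit, rRNA removal, read length, trimming, treatment of reads that map to several places and the way coverage was built are not given in the sources used here. Bowtie 1.0.0, DESeq2 (version and role not given in the sources used here) and the build ASM584v2 are listed per the submitters' processing notes. The deposited line names carry the word Cra while the labels call the strain wild type, and coverage of cra ran through its stop codon in all 4 libraries.

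The deposited values are log2 coverage for each position and strand, to 2 decimals, with no scaling between libraries. All values under 5 fell within 0.005 of the log2 of a whole number, so a value of 0 is a coverage of 1, and positions with no line were taken as a coverage of 0. Positions counted from 0 and were shifted by 1 to match ASM584v2. Coverage was turned back to linear scale and averaged over each gene of the RefSeq table for ASM584v2 (4651 genes). That table gives no strand, so each gene was assigned the strand with the higher mean coverage over the 4 libraries. The strand was unresolved, with a ratio between strands under 3, for 627 tested genes (13.9%) and for 127 of the 1856 called genes, and a call for such a gene may belong to a transcript on the other strand. Overlapping genes on one strand share coverage, and near-identical copies cannot be told apart.

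Because the files hold coverage and not read counts, the test for signal values was used. Gene coverage was divided by median-of-ratios factors over protein-coding genes (0.907 and 1.07 for galactose, 0.881 and 1.16 for glucose), and log2(coverage + 1) was fitted with limma-trend, so folds of low genes are understated. Genes with a mean scaled coverage under 1 (29 genes) and 108 rRNA and tRNA genes were not tested. The prior added 5.16 degrees of freedom to the residual 2. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over 4514 genes, 2219 having an unadjusted p below 0.05. The groups, the test, the alternatives, the rule for named genes and 43 gene lists, written from textbook knowledge (700 of 700 symbols matched), were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 43 lists. Camera with an estimated correlation, fry, and camera with each operon counted once were run beside it. An operon was taken as a run of list members adjacent among the annotated genes on the same inferred strand, with no operon annotation. Such units can split a true operon where a strand is unresolved, or join neighbours, as with galS and the mgl genes. By this rule the arabinose and xylose list made 12 units. The estimated-correlation form uses only the residual 2 degrees of freedom, so few lists could pass whatever their correlation. Named genes were the galactose list with cra, crp, galR, galS and spf, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with coverage of at least 10 and groups apart, and up to 4 members of each list with the largest change. Other members given as examples were chosen after their values were seen. They were aldA, cheY, cheZ, crr, cstA, cyaA, dctA, fbaA, flhC, flhD, fliA, fliC, fruA and fruK. The rest were fucK, gapA, gltD, malP, ptsH, ptsI, rhaA, rhaB, rhaD, ssrA, xylA and xylB.

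The step in galK and shares of coverage were compared by an exact 2-sided permutation over the 6 assignments of 4 libraries, whose smallest p is 0.333. The fragment length was taken from isolated stretches of coverage 1 (median 124 to 135 bases), so total coverage equals about 14.3 to 19.4 M fragments. The commonest length was 38 bases (16.1 to 22% of stretches), at which total coverage equals 50.7 to 63.8 M, and how coverage was built is not settled. In glucose library 1, the shallowest, the median gene held about 359 fragment equivalents, a counting error of 5.3%, and the gene at the 5th percentile held 9.13, a counting error of 33%. At 38 bases these errors are 2.8% and 17.6%. The errors cover counting only. Chi-square per degree of freedom between replicates was 4.00 for galactose and 22.2 for glucose, at the median length, with which the value scales. The libraries were counted separately because the series design calls them biological replicates, not because of this value.

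On simulated data for 4495 genes with 200 changed, 87.3% of 110 genes changed by a log2 fold of 1 and 98.9% of 88 changed by 2 were recovered, 10 unchanged genes were called (5.18% of calls), and of the lists the one with 20 shifted members was called. The simulation drew genes independently, with the same dispersion for both sugars, whereas 41.1% of tested genes were called in the data. It checks the code and does not give the rate of false gene or list calls in the data. Alternatives covered scaling to totals, quantile normalization, filters, pseudocounts of 0.25 and 4, summed strands, shared bases left out, robust eBayes, limma-voom on fragment equivalents, the replicate number as a block, a test against a 2-fold change and each library left out. Some planned results are not reported here. The software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.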

Results

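Transcripts of wild-type Escherichia coli K-12 MG1655, the standard laboratory strain, were sequenced after aerobic growth at 37 °C to mid-log phase in M9 minimal medium with 0.2% galactose or 0.2% glucose as the sugar. Each sugar had 2 libraries. The series title places the experiment in work on Cra, the catabolite repressor/activator that controls genes of central carbon metabolism, and the comparison the labels give is galactose against glucose. Total coverage, summed over both strands, was 1975 and 2374 M in the galactose libraries and 1927 and 2423 M in the glucose libraries. This equals about 15.4, 19.1, 14.3 and 19.4 M fragments at the median length of isolated stretches, or 50.7 to 63.8 M at their commonest length of 38 bases. Of the 4651 annotated genes 4514 were tested, 4266 of them protein-coding. Log2 coverage of genes correlated across genes at r = 0.995 between the galactose libraries and 0.993 between the glucose libraries, and at 0.955 to 0.959 between sugars, where genes are not independent replicates. The series design calls the second library of each sugar a biological replicate. The gene p-values rest on the spread between these 4 samples, moderated towards a trend over all genes that adds 5.16 degrees of freedom to 2. That spread is pooled over the sugars. The median absolute log2 difference between replicates was 0.0975 on galactose and 0.167 on glucose.

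Genes that take up and break down galactose were higher on galactose, most of all the high-affinity mgl transporter. Coverage of mglB, the periplasmic galactose-binding protein, was 13390 ± 374 fragments per base on galactose and 157 ± 0.957 on glucose (SD, n = 2), which is 84.9-fold higher with 1 added to coverage (log2 fold change 6.41 ± 0.07, SE). The transporter genes mglA and mglC rose by 5.33 ± 0.08 and 5.10 ± 0.08 on the log2 scale, and galS, which encodes a repressor of this regulon and lies beside mglB, rose by 5.33 ± 0.10. The genes galT, galK and galM, which lead galactose into glycolysis, rose by 3.84 ± 0.11, 3.12 ± 0.07 and 1.37 ± 0.08. The galK and galM values include coverage gained at a step inside galK, described below. Before that step galK coverage was 1684 on galactose and 85.5 on glucose. The falling order of these values along the operon therefore cannot be read without the step. The galactose permease gene galP rose less, by 0.67 ± 0.13, while galU, which makes UDP-glucose, was lower at -0.61 ± 0.09. Of the 11 members of the galactose list 10 rose and 1 fell. The counts were 10 and 1 adjusted over the list alone. The limma camera adjusted p was 5.01e-08, and adjusted p = 0.191 with an estimated correlation. With each operon counted once the list had 5 units, a median of 0.72 in place of 3.76, and camera adjusted p = 0.0259. The units were the gal operon, mgl with galS, and galP, galR and galU alone. The median was thus the value of galR, not of the gal or mgl operon. One of the 10 is galR, the other gal repressor gene, with a log2 fold change of 0.72. Its strand could not be settled (the strands differed by a ratio of 1.32), and its call ended when both strands were summed (adjusted p = 0.23).

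**Figure D1:**
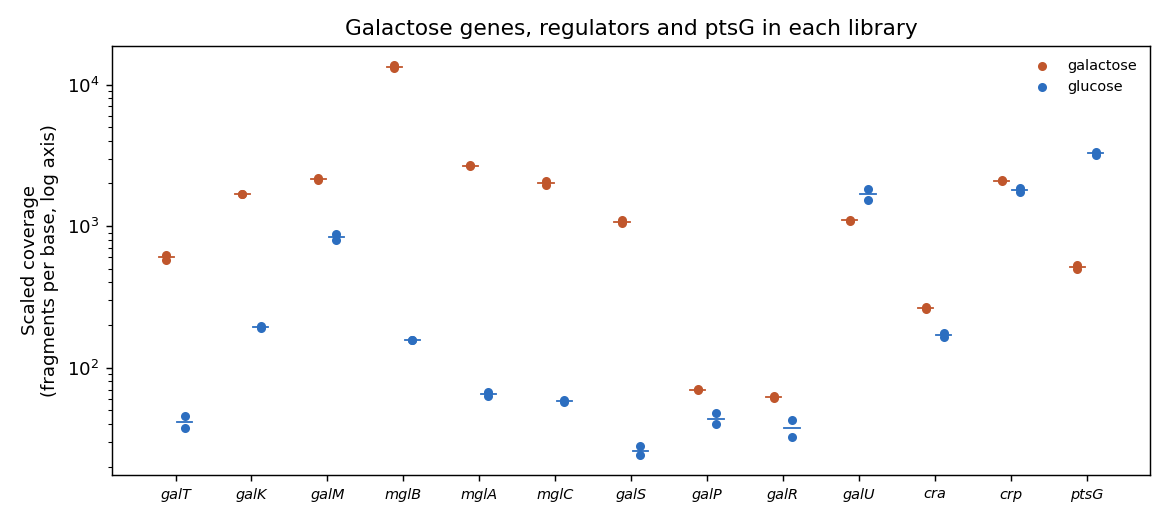
Scaled coverage (fragments per base, log axis) of galactose genes, carbon regulators and ptsG in each library, with points for the 2 libraries of each sugar and a short line at their mean. The points of mglB lie near 13390 on galactose and 157 on glucose, and those of crp near 2093 and 1808.

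Coverage along galK, on the reverse strand of the chromosome at 788831 to 789979 of ASM584v2, was uneven on glucose. At position 789002, 171 bases before the end of galK and found after the values were seen, coverage on glucose stepped from 85.5 ± 9.13 to 1000 ± 48.6 fragments per base and stayed high through galM (SD, n = 2). The position was picked as the largest relative step within galK in the glucose libraries, which favours a large step on glucose. On galactose the same step was from 1684 ± 50.0 to 2522 ± 22.2. The coverage gained across the step was 915 ± 57.8 on glucose and 837 ± 27.7 on galactose, with an exact 2-sided permutation p of 0.333, the smallest that the 6 assignments of 4 libraries can give.

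**Figure D2:**
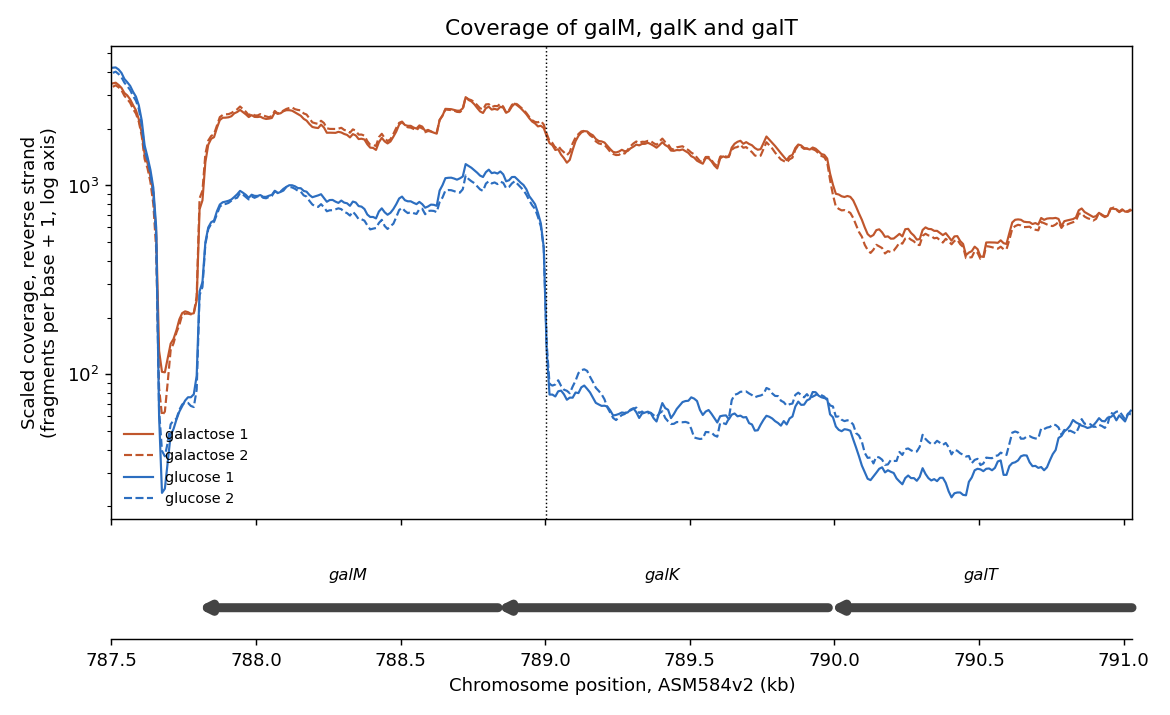
Scaled reverse-strand coverage (fragments per base plus 1, log axis) across galM, galK and galT in the 4 libraries, averaged over 10 bases, with arrows for the genes in the direction of transcription and a dotted line at position 789002. On glucose the coverage rises at the dotted line and stays high through galM, while on galactose it is high on both sides of the line.

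Across the genome 903 genes were higher and 953 lower on galactose (limma-trend, Benjamini-Hochberg adjusted p below 0.05), and 2658 were not called. Of the called genes 428 rose and 114 fell by at least 2-fold, and 217 and 35 passed a limma test against a 2-fold change. Without galactose library 2 the number of lower genes was 602. The 2 galactose libraries lay on one side of both glucose libraries for 3225 genes (71.4%), where chance gives 33.3%. The genes with the largest rises, beside mglB and mglA, belonged to 3 operons. They were prpB, prpD, prpC and prpE of propionate breakdown at 6.89, 6.38, 5.73 and 5.42, tnaC and tnaA of tryptophan breakdown at 5.57 and 5.46, and yjcH and actP, which share an operon with the acetate enzyme gene acs, at 5.54 and 5.48. Coverage of 3 prp genes on glucose rested on few fragments, about 5.86 and 16.3 for prpB, 8.91 and 17 for prpC and 1.98 and 9.76 for prpD in the 2 libraries at the median length. With a pseudocount of 4 their values were 5.74, 4.58 and 4.79, and with fragment equivalents in limma-voom 7.60, 6.48 and 8.02, so their folds are imprecise. For prpD the value was 7.49 with a pseudocount of 0.25, and with both strands summed prpD was at 5.44 and prpC at 5.12. Coverage of the leader gene tnaC on glucose was 6.20 and 16.2 fragments per base, and its value was 4.94 without glucose library 1 and 6.18 without glucose library 2. The largest falls were in azuC at -4.30 ± 0.26, ybfA at -3.22 ± 0.16, glnK, a nitrogen-signalling protein, at -3.02 ± 0.22, and drpB at -3.00 ± 0.17. They were followed by yjcB, yhcN, ptsG, bhsA, mqo and psiE at -2.89 to -2.35. With both strands summed yjcB was at -1.85 and yhcN at -2.02, and with a pseudocount of 4 glnK was at -2.38.

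The glucose transporter gene ptsG was 3261 ± 136 fragments per base on glucose and 514 ± 19.3 on galactose, 6.33-fold lower (log2 fold change -2.66 ± 0.07, limma adjusted p = 5.84e-07). The mannose transporter gene manX was lower at -0.81, crr at -0.48 and ptsI at -0.37, while ptsH stood at -0.05 and was not called. The small RNA sgrS, which acts on ptsG mRNA under sugar-phosphate stress, and its encoded peptide gene sgrT rose by 1.77 and 1.79. The gene sgrT lies within sgrS and shares its coverage, so their rises are not independent, though the list counts both. In this glucose phosphotransferase list 3 of 10 members rose and 5 fell, or 3 and 6 adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.217).

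Most of the textbook genes that Cra activates were higher on galactose, and 7 of 8 rose, also adjusted over the list alone. They were led by pck of gluconeogenesis at 3.70 ± 0.09, the glyoxylate shunt genes aceA, aceK and aceB at 2.58, 2.23 and 1.55, and ppsA at 1.45. The gene fbp, for fructose bisphosphatase, was at -0.13 and not called, with adjusted p = 0.0408 without glucose library 1. The list passed camera at adjusted p = 2.29e-05, with adjusted p = 0.191 with an estimated correlation. Among 21 textbook genes that Cra represses 5 rose and 9 fell, or 7 and 11 adjusted over the list alone. This list was not called (camera adjusted p = 0.256). The fructose genes fruB, fruK and fruA rose by 0.59, 0.50 and 0.33 and glk by 0.60, whereas gpmM was lower at -1.56 and pfkA, tpiA, fbaA and gapA at -0.54 to -0.47. The 2 lists were tested each against other genes, and the difference between them was not tested. Lists overlap, so results for lists that share genes are not separate evidence. For example, pck returns in gluconeogenesis, aceA in the glyoxylate list, and gpmM and pfkA in glycolysis.

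Among the other regulator genes cra rose modestly and crp was not called. Coverage of cra was 265 ± 6.80 on galactose and 170 ± 7.01 on glucose (log2 fold change 0.64 ± 0.09, limma adjusted p = 9.57e-04). The cAMP receptor gene crp was at 0.21 ± 0.07 with adjusted p = 0.0510, just outside the threshold. It passed without glucose library 1 (0.0322) or 2 (0.0093), with total scaling (0.0418), quantile normalization (0.00494), a coverage filter of 10 (0.0471), limma-voom (0.0377), the replicate block (0.0383) and without strand-unresolved genes (0.0334). The adenylate cyclase gene cyaA was lower at -0.53, csrA at -0.80, and spf, the small RNA Spot 42, at -0.75 ± 0.11. Of 13 carbon regulators 4 rose and 2 fell, or 5 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.248, or 0.0294 after quantile normalization).

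Most genes of the TCA cycle, the glyoxylate shunt and acetate metabolism were higher on galactose. In the TCA cycle 15 of 17 genes rose and 1 fell, also adjusted over the list alone. The camera adjusted p was 1.44e-06, and adjusted p = 0.340 with an estimated correlation. The list was led by fumA at 1.80, sdhC at 1.57 and fumC at 1.55, and mqo, a malate:quinone oxidoreductase, was lower at -2.45. In the glyoxylate list 7 of 8 rose, also adjusted over the list alone, among them the glycolate genes glcD and glcE at 3.74 and 3.57. Here adjusted p = 1.65e-06, and adjusted p = 0.191 with an estimated correlation. Of 10 pyruvate dehydrogenase and acetate genes 6 rose, also adjusted over the list alone (adjusted p = 0.00485, adjusted p = 0.475 with an estimated correlation). The gene acs was at 4.32, and the list call ended when each operon was counted once (adjusted p = 0.094). Of 9 ATP synthase genes 8 rose by small amounts, up to 0.57 for atpB, also adjusted over the list alone. The list had adjusted p = 0.003, and adjusted p = 0.241 with an estimated correlation. That call ended without galactose library 1, at a list median of 0.39 in place of 0.37. The call also ended with the operon counted once (camera adjusted p = 0.299). The list was then 1 unit, which could hardly pass, so that loss says little about the list.

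Glycolysis and the pentose phosphate pathway held more falls than rises but neither list was called by camera. Directional fry, which does not compare a list with other genes, called both lower (fry adjusted p = 0.011 and 0.0128). In glycolysis 3 of 14 rose and 8 fell, or 5 and 9 adjusted over the list alone (camera adjusted p = 0.129). In the pentose phosphate and Entner-Doudoroff list 1 of 12 rose and 5 fell, also adjusted over the list alone, with gnd at -1.17 and zwf at -0.62 (camera adjusted p = 0.137, and 0.0473 without glucose library 1). In gluconeogenesis 3 of 7 rose, also adjusted over the list alone, namely pck, ppsA and maeB (camera adjusted p = 0.0628, and 0.00108 and 0.0298 without galactose library 1 or 2 and 0.0206 after quantile normalization). In the respiratory chain 15 of 24 rose and 4 fell, or 16 and 4 adjusted over the list alone, with nuoA at 0.87 and ndh at -1.07 (camera adjusted p = 0.0736, and 0.00916 without glucose library 2 and 0.0118 after quantile normalization). With each operon counted once its direction turned, with a median of -0.08 over 5 units in place of 0.37 (adjusted p = 0.732).

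Many transport and breakdown genes for sugars that were not supplied also rose on galactose, but not all. Of 7 lactose and melibiose genes 7 rose, also adjusted over the list alone, with lacZ at 4.31 ± 0.18 (3.42 with a pseudocount of 4) and melA at 3.47 ± 0.13 (camera adjusted p = 1.19e-05, adjusted p = 0.191 with an estimated correlation). For hexitols and galactitol 13 of 16 rose, or 14 adjusted over the list alone, led by gatD, gatB, gatC and gatA at 3.11, 2.90, 2.75 and 2.64 (adjusted p = 5.01e-08, adjusted p = 0.191 with an estimated correlation). With each operon counted once the hexitol and galactitol median was 0.85 in place of 1.65 (adjusted p = 0.00732). For ribose, fucose and rhamnose 12 of 20 rose, also adjusted over the list alone, among them fucO at 2.67 and rbsB at 2.18 (adjusted p = 3.40e-05, adjusted p = 0.191 with an estimated correlation). For arabinose and xylose 10 of 16 rose and 2 fell, also adjusted over the list alone. Highest were araF at 3.56 and xylF at 2.43, or 1.71 with a pseudocount of 4 (adjusted p = 0.00502, adjusted p = 0.380 with an estimated correlation, and 0.0768 with each operon counted once). The strand of 7 of those 16 genes was unresolved, xylE among them. Some breakdown genes were not called, among them xylA, xylB and fucK at 0.22, -0.05 and -0.02. Nor were rhaA, rhaB and rhaD, whose strands were unresolved.

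Sugar acid, trehalose and maltose genes were also mostly higher. Of 19 sugar acid genes 13 rose and 2 fell, also adjusted over the list alone, with idnD at 2.40, or 1.65 with a pseudocount of 4, and gntP at 1.97 (camera adjusted p = 0.00253, adjusted p = 0.218 with an estimated correlation). Of 15 amino sugar and trehalose genes 8 rose, also adjusted over the list alone, led by treB at 2.99 and treC at 2.43 (adjusted p = 0.00326, adjusted p = 0.218 with an estimated correlation). In the maltose regulon 7 of 11 rose and 3 fell, also adjusted over the list alone. The extremes were lamB at 2.68 and malE at 2.30 against malP at -0.81 (adjusted p = 0.0466, adjusted p = 0.307 with an estimated correlation). The maltose call also ended with total scaling (0.0537), without glucose library 2 (0.0697) and with each operon counted once (0.327, median 0.43 in place of 1.36). For glycerol 3 of 11 rose and 2 fell, also adjusted over the list alone, with glpK at 1.94 (camera adjusted p = 0.271).

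The list of dicarboxylate, lactate and other carbon uptake held 16 of 21 genes that rose, or 17 adjusted over the list alone, and none that fell (camera adjusted p = 1.61e-11, adjusted p = 0.191 with an estimated correlation). Its median was 1.65, and 2.44 without strand-unresolved genes. Besides the prp and tna genes it held aldA, an aldehyde dehydrogenase, at 3.38, the peptide and pyruvate transporter cstA at 3.37 and dctA at 2.41. All 9 fatty acid degradation genes rose, also adjusted over the list alone, with fadB at 3.69 ± 0.12, fadA at 3.40 ± 0.09 and fadH at 3.07 ± 0.14 (adjusted p = 5.01e-08, adjusted p = 0.191 with an estimated correlation).

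**Figure D3:**
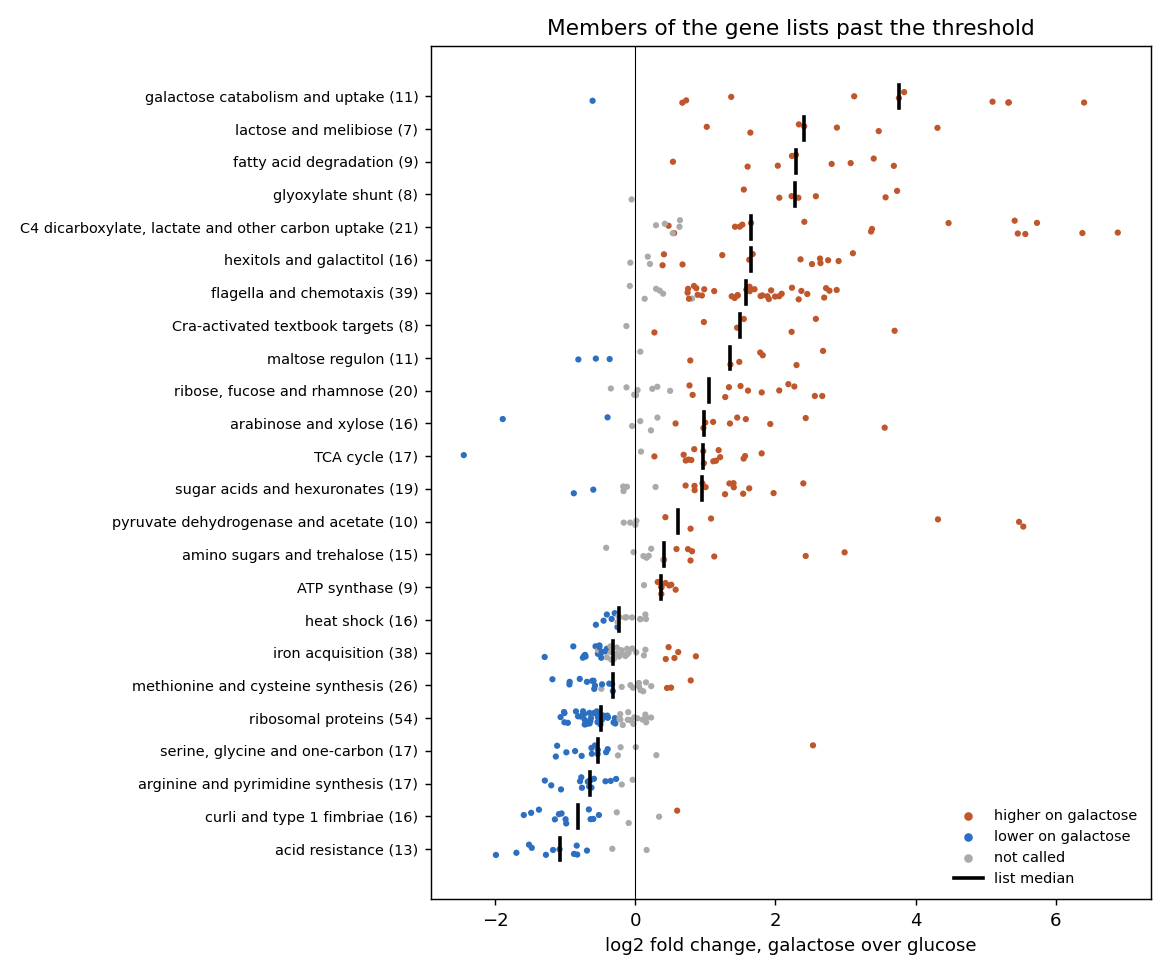
Log2 fold change (galactose over glucose) of each measured member of the 24 gene lists past the camera threshold, coloured by the call of each gene, with the list median as a black bar and the number of members in parentheses. The medians run from 3.76 for the galactose list to -1.08 for acid resistance. The former was 0.72 with each operon counted once, which is the value of the single gene galR. With an estimated correlation no list passed camera, at adjusted p = 0.191 or more. The estimated-correlation test has only 2 degrees of freedom.

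Motility genes rose and surface fimbriae fell. Of 39 flagellar and chemotaxis genes 33 rose, or 34 adjusted over the list alone, among them flgE at 2.87 ± 0.14, the flagellar sigma factor gene fliA at 2.45, flagellin fliC at 1.91 ± 0.08 and the master regulator genes flhD and flhC at 0.89 and 0.74. The camera adjusted p was 2.96e-12, and adjusted p = 0.191 with an estimated correlation. The chemotaxis genes cheY and cheZ were at 0.40 and 0.30 and not called. Of 16 curli and type 1 fimbrial genes 12 fell and 1 rose, also adjusted over the list alone. Lowest were the fimbrial subunit fimA at -1.59 ± 0.07 and the usher fimD at -1.49 ± 0.15 (adjusted p = 3.03e-04, adjusted p = 0.191 with an estimated correlation, and 0.0661 with each operon counted once).

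Ribosomal protein genes and several biosynthetic pathways were lower on galactose. Of 54 ribosomal protein genes 37 fell, or 39 adjusted over the list alone, and none rose. The list median was -0.49, with rpsT, rpsI, rpsU and rplM between -1.07 and -1.01 (camera adjusted p = 6.73e-10, adjusted p = 0.191 with an estimated correlation). Under other scalings the median closest to 0 was -0.303, and lists matched on coverage and length had a median of -0.28. Among translation factors infA and efp were lower at -0.95 and -0.94, whereas rmf and raiA, which act on idle ribosomes, rose 2.84-fold and by 0.94 on the log2 scale. That list had 3 of 13 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.0715, and 0.0489 and 0.0300 without glucose library 1 or 2).

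Of 17 arginine and pyrimidine genes 15 fell, also adjusted over the list alone, with pyrE at -1.29, pyrD at -1.20 and argI at -0.79 (camera adjusted p = 8.33e-07, adjusted p = 0.218 with an estimated correlation). In the serine, glycine and one-carbon list 12 of 17 fell and 1 rose, or 13 and 2 adjusted over the list alone. The values were serC at -1.14 and serA at -1.12 against aspartase gene aspA at 2.54 (adjusted p = 2.12e-04, adjusted p = 0.191 with an estimated correlation). In the methionine and cysteine list 13 of 26 fell and 3 rose, or 14 and 3 adjusted over the list alone. Among them sbp was at -1.19 and metE at -0.94 (adjusted p = 0.0109, adjusted p = 0.241 with an estimated correlation, and 0.292 after quantile normalization and 0.204 with each operon counted once).

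Acid resistance genes fell, 11 of 13 of them, also adjusted over the list alone, with hdeD at -1.99 ± 0.08 and the regulator gene gadE at -1.52 ± 0.15 (camera adjusted p = 1.44e-06, adjusted p = 0.241 with an estimated correlation). The genes gadA and gadB, at -1.48 and -1.70, are near-identical copies whose reads may not have been told apart. Of 38 iron acquisition genes 14 fell and 5 rose, or 16 and 5 adjusted over the list alone. They included fiu at -1.30 and fepA at -0.89 against fhuF at 0.86 (adjusted p = 0.00589, adjusted p = 0.267 with an estimated correlation). Of 16 heat shock genes 6 fell, also adjusted over the list alone, clpX most at -0.56 (adjusted p = 0.0476, adjusted p = 0.503 with an estimated correlation). The heat shock call also ended without galactose library 1 or 2 (0.165 and 0.157), without glucose library 1 (0.0705), with total scaling (0.0537), with quantile normalization (0.468), without strand-unresolved genes (0.086) and with each operon counted once (0.103).

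Nitrogen genes split, with 12 of 22 higher and 6 lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.137). The dipeptidase gene ddpX and the amino acid transport gene argT rose by 3.01 (2.27 with a pseudocount of 4) and 2.05, while glnK and the glutamate synthase gene gltD were lower at -3.02 and -1.05. For branched-chain amino acids 7 of 17 rose and 6 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.866). For aromatic amino acids and histidine 2 of 20 rose and 4 fell, or 1 and 4 adjusted over the list alone (adjusted p = 0.490). For purines 1 of 15 rose and 6 fell, also adjusted over the list alone, with purA at 0.93 and guaB at -0.83 (adjusted p = 0.0715, and 0.00941 without glucose library 1). For phosphate starvation 1 of 13 rose and 3 fell, or 1 and 1 adjusted over the list alone, with ugpB at 1.02 (adjusted p = 0.617).

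General stress genes of the RpoS list were mostly not called, with 2 of 21 higher and 6 lower, also adjusted over the list alone, and osmY lowest at -1.71 (camera adjusted p = 0.137). In the SOS and prophage list 3 of 17 rose and 3 fell, also adjusted over the list alone, with tisB at 1.57 and sulA at 2.08, whose strand was unresolved (adjusted p = 0.866). For glycogen 3 of 6 rose, or 4 adjusted over the list alone (adjusted p = 0.0738, 0.0117 without glucose library 2 and 0.0135 after quantile normalization). For colanic acid 3 of 18 fell, or 1 adjusted over the list alone (adjusted p = 0.248), and the strand was clear for 6 of the 18. Of 26 small RNAs 6 rose and 7 fell, or 6 and 8 adjusted over the list alone, with glmY at 1.12 and csrC at -1.02 (adjusted p = 0.860).

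Of the coverage of protein-coding genes 2.75 ± 0.127% lay on the opposite strand on galactose and 2.70 ± 0.190% on glucose (SD, n = 2, exact permutation p = 0.667). Each gene had been given the strand with the higher coverage, so the opposite strand is the lower by construction and these shares may be too low. The tmRNA gene ssrA took 14.1 and 15.1% of all coverage on galactose and 11.8 and 10.3% on glucose. Genes for tRNA took 0.759 ± 0.0076% and 1.38 ± 0.0663%, and rRNA genes 0.0923 ± 0.019% and 0.144 ± 0.0475%, each with an exact permutation p of 0.333, the smallest possible here.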

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

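The search for coverage outside annotated genes was chosen after the main results were seen, and its differences between the sugars were not tested. Among 35430 windows of 100 bases at least 200 bases from any gene on their strand, 19 regions were at least 8-fold higher on galactose in both libraries and 0 were lower by the same rule. Of these 18 lay opposite a gene, and 14 of the 18 held 1.40 to 2.48% of the galactose coverage of the other strand over the same bases, near the 0.0205 that was the median opposite-strand gain of the risen genes relative to their own. These 14 are therefore not evidence of transcription outside genes. The 3 regions with the largest gain are given here, with folds of the group means after 1 was added to each mean. The forward strand at 1489901 to 1490200, opposite gapC and downstream of aldA, held 326 fragments per base on galactose and 25.6 on glucose, 12.31-fold higher and 89.6% of the other strand on galactose, while aldA itself rose by 3.38 on the log2 scale. The forward strand at 3552701 to 3552800, between malP and malT, held 200.7 and 15.7, 12.09-fold higher, with malT at 0.78. The forward strand at 2238601 to 2240500, opposite mglA and mglB, held 174 and 3.77, 36.71-fold higher but 1.88% of the other strand on galactose, where mglB on its own strand held 13390 and 157.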

How the results depend on the processing

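Leaving out strand-unresolved genes, leaving the galactose and glyoxylate lists out of the odds ratio and combining an estimated correlation with the replicate block were chosen after seeing the data, and the other alternatives before. Tested against a 2-fold change, 217 genes were higher and 35 lower, fewer because that test asks for more than any change. Leaving out each library in turn gave 662 to 1018 higher and 602 to 1068 lower genes, of which 418 to 475 and 122 to 137 by at least 2-fold, and 16 to 17 lists higher and 7 to 10 lower. Without galactose library 1 or 2, 1338 of 1401 and 1242 of 1264 calls were shared with the full set, without glucose library 1 or 2, 1690 of 1913 and 1721 of 2086, and 0 reversed. In these fits the lone library is assumed to vary like the other group. With an estimated correlation 0 lists were higher and 0 lower, and likewise with the block added. That form rests on the residual 2 degrees of freedom, and fewer with the block, so it could hardly pass any list. The estimates varied in sign, at -0.0955 for the galactose list and 0.607 for the pyruvate dehydrogenase and acetate list. The lost calls therefore do not show that correlation within lists accounts for them, nor do they exclude it. Fry's mixed test, which has no direction, passed 22 lists that camera places higher and 20 it places lower, and counting each operon once gave 12 and 5. Directional fry, which does not compare a list with other genes, called 8 lists that camera did not and missed 1, heat shock. Of the 8, the glucose phosphotransferase, Cra-repressed, glycolysis and pentose phosphate lists were lower. The glycerol, gluconeogenesis, nitrogen and carbon regulator lists were higher. The small RNA list had a positive median and mean but a negative camera direction, and the SOS list a median of -0.04 and a mean of 0.18 with a positive one, neither being called. With each operon counted once the nitrogen median was -0.10 in place of 0.76, and the phosphate direction turned from down to up, again with no call. The opposite-strand share fell to 2.26% on galactose and 2.31% on glucose among genes with no opposite gene within 200 bases, and the cause was not tested. Quantile normalization moved the median fold change by -0.12 and gave 733 higher and 1121 lower genes. Same-numbered libraries shared little (correlation of deviations 0.0636, across genes), so the numbers were not taken as pairs. With the replicate number as a block 1063 genes were higher and 1117 lower, 435 and 117 by at least 2-fold, 1853 calls being shared with the fit without it, and 17 lists were higher and 7 lower, heat shock losing its call (adjusted p = 0.109) and gluconeogenesis gaining one (0.00533). The blocked fit has fewer residual degrees of freedom, and its added calls are not stronger evidence. The limma adjusted p of hisC, with 41.0 and 73.8 on glucose, went from 0.0833 to 9.29e-05 at the same log2 fold change of 0.62. Of 182 named genes none reversed, 91 lost their call in the test against a 2-fold change, and some lost it when a library was left out. In glucose library 1 the counting error was 33% for the gene at the 5th percentile and 5.3% for the median gene, at the median length. Calls were not compared by coverage.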

Other observations

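The genes in the first paragraphs, the step in galK, the position bias and additional transcript tests, and the tests of scaling and carbon genes for the excess of rises were chosen after the result was seen, while the unstranded signal test and both ribosomal tests were set before. Some genes that no list held were also higher on galactose. The galactofuranose transporter genes ytfQ, ytfR, ytfT and yjfF were at 4.43, 2.88, 2.58 and 1.94 on the log2 scale, and the galactonate genes dgoA, dgoD, dgoT, dgoK and dgoR at 3.68, 3.41, 2.92, 2.44 and 1.65 (limma adjusted p = 7.2e-05 or less for each, highest in dgoR). The autoinducer-2 genes lsrA and lsrB were at 3.44 and 3.05 and the aldehyde dehydrogenase gene aldB at 3.57.

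The outer membrane protein gene ompX was 4.02-fold lower on galactose (2777 ± 56.4 against 11181 ± 1181 fragments per base, SD, n = 2), ompC was at -0.72 and ompF at 0.57. The small RNA sdsR was at 1.82, and the overlapping ryeA and azuR loci at 1.80 and -4.27 share their coverage with sdsR and azuC. The toxin-antitoxin genes hokB and mokB were both at 2.67, and cspD was at 2.56. All 12 copies of the IS5 gene insH were higher, at 1.34 to 1.83, but they share reads and are not independent.

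The word Cra in the names inside the deposited files left open whether the strain carries a tagged Cra. Coverage over the last 50 bases of cra and the next 50 bases was 149 and 155, 153 and 153, 83.8 and 78.9, and 89.2 and 80.3 fragments per base in galactose 1 and 2 and glucose 1 and 2, with no gap at the stop codon. What these values say of the strain was not tested.

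On glucose, coverage in galK stepped from 85.5 ± 9.13 to 1000 ± 48.6 fragments per base at position 789002, and on galactose from 1684 ± 50.0 to 2522 ± 22.2. A position-specific fragment bias would multiply both sugars alike, but the ratio below to above the step was 7.88 times higher on glucose, which argues against it. The position was picked for its large ratio on glucose, so the size of this difference is overstated to an unknown degree. The gain across the step was 837 ± 27.7 on galactose and 915 ± 57.8 on glucose, a ratio of 0.915, so a candidate explanation is an additional transcript that starts near the end of galK and is made on both sugars. A processed or more stable end of the mRNA stays open, and transcript ends were not mapped.

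More genes rose than fell by at least 2-fold. The ratio of rises to falls was 3.75, and 2.39 at its lowest under other scalings, which argues against scaling as the whole cause. The median opposite-strand gain of the risen genes was 0.0205 of their own-strand gain, which argues against unstranded signal such as DNA. Genes of 12 lists (galactose, lactose and melibiose, maltose, arabinose and xylose, ribose with fucose and rhamnose, glycerol, sugar acids, hexitols, amino sugars, fatty acids, dicarboxylates and other carbon uptake, and the glyoxylate shunt) made up 92 of 164 measured members among the rises and 336 of 4350 other genes (Fisher's exact odds ratio 15.2, 95% interval 10.8 to 21.5, p = 7.30e-54, with genes of an operon not independent). Without the galactose and glyoxylate lists 77 of 145 members rose by at least 2-fold (Fisher's exact odds ratio 13.5, 95% interval 9.44 to 19.4, p = 1.56e-43). A candidate explanation is that carbon-source genes are held low on glucose, but the test does not tell this from induction by galactose. It is a hypothesis found and tested on the same data, and 336 of the 428 rises lay outside those lists.

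The fall of ribosomal protein genes was set against coverage, length and scaling. Of 10000 random lists matched on coverage and length, the observed median of -0.49 lay at percentile 0.65, the matched lists having a median of -0.28 and a range of -0.59 to 0.12. Such a trend may account for part of the fall. The random lists were not matched on operons, while the 54 genes form 22 operon units. Their spread may therefore be too narrow, and whether the trend accounts for all of the fall is not settled. Under other scalings the list median closest to 0 was -0.303, which argues against scaling as the whole cause. That value is near the matched median of -0.28, and trend and scaling together were not tested. An effect of the sugar itself stays open, as untested.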
